A study of Mus musculus with 12 samples.

How the data were processed

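Expression was measured by RNA sequencing on an Illumina system in 12 libraries of sorted mouse lung ILC2s. The authors deposited, for each of the 2 experiments, a table of estimated counts per gene and a table of the same genes as CPM, counts scaled to a library total. The submitters' processing notes name bcl2fastq 2.17.1.14, Partek and STAR 2.5.3a with the mm10 genome; which tool made the counts and which gene annotation was used are not given in the sources used here. Gene positions are those of the deposited tables. Of the estimated counts, 47.9% (KO and WT) and 44.4% (sorted fractions) were not whole numbers within a tolerance of 0.001, as an estimate that shares reads between genes gives. The deposited CPM equals the count divided by a library total plus 0.0001. Its columns sum to 868953 to 900057, so the tables list 86.9% to 90.0% of the counts behind that scaling. The tables list 18601 genes for KO and WT and 21361 for the sorted fractions, where 20 gene symbols had been turned into dates and 17 were restored through their gene identifier.

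Groups were taken from the sample labels. The estimated counts were rounded and each experiment was analysed from its own 6 libraries. Genes were filtered with filterByExpr, libraries scaled by TMM, and groups compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values in the text are scaled by TMM. Log2 fold changes are KO minus WT and LAIR-1- minus LAIR-1+, so that in both comparisons the group lacking LAIR-1 is set against its reference. The labels name no sort by LAIR-1 for the WT libraries, which may hold cells with and without surface LAIR-1. Standard errors of log2 fold changes come from the same F statistic. The difference between the comparisons was tested in 1 edgeR fit of the 4 group means. No term for replicate was used, since the labels do not pair the libraries. For genes without a count in 1 group, a fold is given as a lower bound against a floor of 3 counts over that group; this covers counting error only.

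Before the data were examined, 33 lists holding 578 genes (pathways, markers of other cell types, and checks of RNA quality and sex), the groups, tests and most alternatives were fixed. Lists with at least 3 tested genes were compared with the other genes by camera (preset correlation of 0.01), again with an estimated correlation, and by fry, whose p asks whether a list moves one way on balance. The genes to name were fixed by rule. They were Lair1, 16 ILC2 genes (Il4, Il5, Il9, Il13, Areg, Csf2, Gata3, Rora, Il1rl1, Il7r, Il2ra, Klrg1, Icos, Arg1, Pdcd1 and Mki67), and up to 4 members per list that passed. Added to these were the 10 highest and 10 lowest fold changes among genes that passed with a mean log2 CPM of at least 3 and no overlap between groups, leaving out predicted genes and receptor segments. Members that a list adds and that did not pass with each library left out are named only in part. Between the comparisons the rule took up to 5 genes per direction that passed in both and the 5 with the smallest p for the difference.

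Alternatives fixed in advance were median-of-ratios size factors, library totals alone, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom with quality weights and limma-trend on the authors' CPM with an offset of 1 or 0.1 (limma 3.58.1), all 12 libraries in 1 fit, a test against a 1.2-fold change, an unadjusted p for the overlap, and leaving out each library in turn. Chosen after seeing the data were filters at a mean of at least 20 and at least 50 CPM, robust estimation of the spread, the list tests of the difference, and the alternatives run on the unadjusted overlap.

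The tests were tried on simulated counts with the means, depths and spread of each experiment and 200 genes changed 1.5-, 2- or 4-fold. The changed genes were drawn from those with an average of at least 5 CPM, so recovery of weaker genes was not tried. In KO against WT, edgeR recovered 5.97%, 38.8% and 78.8% of these, with 4 unchanged genes called. At a mean of at least 50 CPM, where 32, 31 and 37 of the changed genes were tested, it recovered 37.5%, 93.5% and 100%, with 4 unchanged genes called. DESeq2 recovered 26.9%, 59.7% and 90.9%, with 67 unchanged genes called. Between the sorted fractions edgeR recovered 71.6%, 95.5% and 100%, with 5 unchanged genes called and 16 by DESeq2. For the difference, where 134, 129 and 125 genes changed in either experiment differed by these folds, it recovered 7.46%, 38.0% and 80.8%, with 27 unchanged genes called. Every column of both tables was used.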

Results

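RNA was sequenced from group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines without an antigen receptor. The cells were sorted from the lungs of C57BL/6 mice aged 8 weeks that had received 3 intranasal doses of recombinant IL-33 (0.5 µg per mouse), and were then held for 24 hours with IL-2 and IL-7 at 10 ng per mL each. LAIR-1 is an inhibitory receptor for collagen that carries immunoreceptor tyrosine-based inhibitory motifs. Per the labels, 12 libraries fall into 4 groups of 3: ILC2s of wild-type (WT) mice (libraries 9, 10 and 11), ILC2s of mice lacking LAIR-1 (KO; libraries 13, 14 and 15), and WT ILC2s separated into cells with surface LAIR-1 (LAIR-1+; libraries 1, 2 and 3) and without it (LAIR-1-; libraries 7, 8 and 10). The labels do not say whether the replicates are separate animals or how the sorted fractions pair, so p-values measure the spread between these samples.

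Depth was similar across groups. The WT and KO libraries held between 18061470 (WT 10) and 20878649 (KO 13) estimated counts, and the sorted libraries between 18885002 (LAIR-1- 7) and 28290487 (LAIR-1- 10). Mitochondrially encoded mRNAs took 0.416% of the counts of WT 11, against 0.736% to 0.822% in the other 5 WT and KO libraries and 0.840% to 1.21% in the sorted ones. WT 11 also had 17557 genes with a count, against 15300 and 15641 in WT 9 and WT 10. In a principal component analysis of the WT and KO libraries, WT 9 stood apart on the first component (35.2% of the variance) and WT 10 on the second (25.9%). Log2 CPM correlated at r = 0.857 between WT 9 and WT 10, at 0.908 to 0.920 between the KO libraries, and at 0.935 to 0.945 between WT 11 and the KO libraries. The pairs of sorted libraries were at 0.970 to 0.984. The biological coefficient of variation in edgeR was 0.505 in KO and WT and 0.135 in the sorted fractions. The experiments differed in the sex-linked transcripts. Xist, transcribed from the inactive X chromosome, lay between 57.6 and 91.7 CPM in each WT and KO library and at 0.371 CPM or lower in each sorted library. The Y-linked Ddx3y reached 40.4 to 55.2 CPM in the sorted libraries. Ribosomal protein genes took at most 1.42% of the counts in WT and KO and 2.97% to 3.72% in the sorted libraries.

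Lair1 itself (protein coding, minus strand of mm10 chromosome 7, 4003402 to 4063204) was low in all 12 libraries. It reached 3.75, 11.1 and 7.66 CPM in WT 9, 10 and 11, and 0.427, 0 and 3.28 CPM in KO 13, 14 and 15, where counts were 9, 0 and 67. The library labelled KO 15 thus held nearly as much Lair1 as WT 9, which had 70 counts. The log2 fold change of KO against WT was -2.59 ± 1.47 (SE, n = 3 per group) and did not pass the edgeR test (adjusted p = 0.715), although the 3 KO libraries were below the 3 WT libraries. Between the sorted fractions, Lair1 was 8.71, 12.4 and 12.2 CPM in LAIR-1+ 1, 2 and 3, and 1.10, 0.577 and 1.95 CPM in LAIR-1- 7, 8 and 10. This difference of -3.14 ± 0.34 on the log2 scale passed (adjusted p = 0.000346), with every LAIR-1- library below every LAIR-1+ library.

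**Figure D1:**
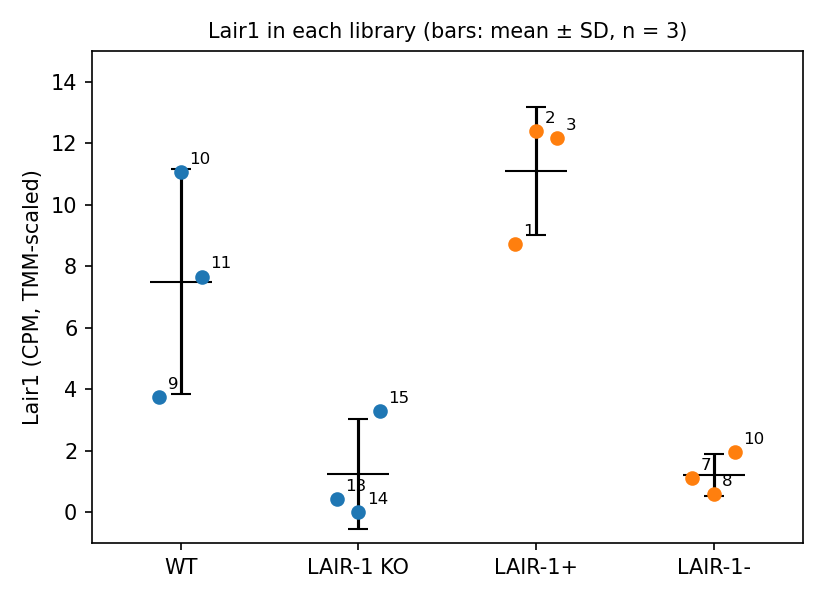
Lair1 in each library, in CPM on a linear axis, by group. Points are libraries with their replicate number and bars are the mean with its SD (n = 3); the library labelled KO 15 (3.28 CPM) lies near WT 9 (3.75 CPM).

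The first comparison asked how ILC2s lacking LAIR-1 differ from WT ILC2s in mRNA content. Pxdc1, a gene for a protein with a phosphoinositide-binding PX domain (minus strand of chromosome 13, 34627834 to 34653486), fell from 740 ± 50.8 to 296 ± 21.8 CPM (SD, n = 3), a log2 fold change of -1.32 ± 0.09 (SE). It was the 1 gene of 14164 past an adjusted p of 0.05 (adjusted p = 0.0264). Il5, the eosinophil growth factor that ILC2s make in bulk, was at 5007 ± 529 CPM in WT and 9065 ± 1276 CPM in KO. Csf2, which encodes GM-CSF, was at 678 ± 76.3 and 1130 ± 68.7 CPM, and for both genes the 3 KO libraries lay above the 3 WT libraries. Tnfrsf8 (CD30) was at 37.6 ± 4.29 and 137 ± 36.2 CPM, Tnfrsf9 (CD137) at 78.8 ± 15.1 and 230 ± 28.9 CPM, and Il1r2, the decoy receptor for IL-1, at 97.7 ± 17.4 and 257 ± 2.54 CPM. Over all 14164 genes these 5 did not pass (adjusted p = 0.141 for Tnfrsf8, Tnfrsf9 and Il1r2, 0.163 for Csf2 and 0.176 for Il5).

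When the test was restricted to the 4723 genes with a mean of at least 50 CPM, a filter chosen after the data were seen, 55 genes passed in KO against WT, 25 higher and 30 lower, Pxdc1 included. The receptors Tnfrsf8 (1.86 ± 0.21, adjusted p = 0.00272), Tnfrsf9 (1.53 ± 0.16, adjusted p = 0.00162) and Il1r2 (1.39 ± 0.14, adjusted p = 0.00154) rose, as did Il5 (0.85 ± 0.10, adjusted p = 0.00432) and Cpd, a carboxypeptidase gene (1.21 ± 0.16, adjusted p = 0.00532). Together with Pxdc1 and the predicted gene Gm42047, these were the 7 genes that passed there with any 1 of the 6 libraries left out. Other genes passed there with all 6 libraries and not in each of those smaller fits. Their highest adjusted p was 0.0510 for Csf2 (0.73 ± 0.10), Kit (-0.75 ± 0.11), Lpcat2 and Prnp, 0.0564 for Il13 (1.13 ± 0.16) and 0.0685 for Srebf1. It was 0.192 for the transcription factor Irf4 (2.05 ± 0.43). The 55 became 23 without WT 9, 17 without WT 10, 49 without WT 11, 67 without KO 13, 7 without KO 14 and 13 without KO 15. These genes were named after their values were seen.

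Among the lists fixed beforehand, 8 of the 26 tested moved together in KO against WT by camera with a preset correlation, and 0 did with an estimated correlation. Adjusted over all genes, 0 members of any list passed. Adjusted over the list alone, 8 of 17 effector cytokines passed: Il13, Csf2, Il5, Il9, Lif and Tnf rose, and Calca and Ltb fell (list adjusted p = 0.000179, adjusted p = 0.0945 with an estimated correlation). Of 18 costimulatory receptors and ligands, 3 rose by that test: Tnfrsf8, Tnfrsf9 and Tnfsf8, which encodes the CD30 ligand (list adjusted p = 3.06e-06, adjusted p = 0.0945 with an estimated correlation). In the unfolded protein and integrated stress response, 6 of 17 rose (list adjusted p = 4.31e-06, adjusted p = 0.0945 with an estimated correlation). They include Asns, the asparagine synthetase gene (0.69 ± 0.10), Hspa5, the main chaperone of the endoplasmic reticulum (0.45 ± 0.10), and Xbp1 (0.60 ± 0.13). In glycolysis and hypoxia response, Tpi1, Pfkl and Pgam1 rose, by 0.54 ± 0.07, 0.43 ± 0.10 and 0.32 ± 0.07, and 20 of 23 did not pass (list adjusted p = 0.000378, adjusted p = 0.0945 with an estimated correlation).

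The lists that fell held redox, lysosomal and lineage genes. In oxidative stress defence, Srxn1, Gclm, Gclc and Nqo1, targets of the transcription factor NRF2, fell and Mt1 rose, with 12 of 17 not past the list-alone test (list adjusted p = 0.000596, adjusted p = 0.269 with an estimated correlation). The median of the list was -0.30 and its mean 0.03. Ctsd and Ctsb, lysosomal cathepsins, fell among 13 genes of autophagy and lysosome (list adjusted p = 0.00600, adjusted p = 0.151 with an estimated correlation). Of 26 ILC2 identity genes, Kit, Ly6a and Gata3 fell and Il7r rose, list-alone (list adjusted p = 0.00600, adjusted p = 0.409 with an estimated correlation). This list did not pass without KO 13 (adjusted p = 0.245). The 13 mitochondrially encoded mRNAs, a measure of RNA quality, were higher (median log2 fold change 0.46, list adjusted p = 5.81e-07, adjusted p = 0.427 with an estimated correlation). Without WT 11, the library with the low mitochondrial share, their median was 0.25, and all 8 lists passed. Areg (-0.39 ± 0.16), Rora (-0.23 ± 0.13), Il1rl1 (-0.09 ± 0.10), Il4 (0.01 ± 0.39) and Pdcd1 (0.30 ± 0.14) did not pass at any of these levels. Nor did Klrg1 (-0.34 ± 0.14), Il2ra (0.17 ± 0.15), Icos (-0.013 ± 0.18), Arg1 (-0.054 ± 0.12) or Mki67 (-0.17 ± 0.15) over all genes.

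Pxdc1 did not pass over all genes with any 1 library left out (adjusted p = 0.101 without WT 9, 0.140 without WT 10, 0.239 without WT 11, 0.0887 without KO 13, 0.421 without KO 14 and 0.428 without KO 15); edgeR then called 0 genes, with 956 to 1560 at an unadjusted p under 0.05. With all 6 libraries 1186 genes were at an unadjusted p under 0.05 where 708 would be by chance, 2290 genes (16.2%) had no overlap between the groups where chance gives 10%, and DESeq2 called 322 genes, limma-voom 2 and edgeR with all 12 libraries in 1 fit 267.

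The second comparison asked how WT ILC2s without surface LAIR-1 differ from those with it. LAIR-1- cells had more Il10, which encodes an anti-inflammatory cytokine (18.7 ± 5.69 against 1.39 ± 0.311 CPM, SD, n = 3), and more Gzma, a granzyme gene also listed among markers of NK cells and ILC1s (91.9 ± 7.69 against 9.81 ± 7.03 CPM). They also had more of the costimulatory receptors Tnfrsf8 (238 ± 8.36 against 91.6 ± 2.42 CPM) and Tnfrsf9 (139 ± 5.69 against 54.9 ± 4.26 CPM). They had less Csf2 (325 ± 12.2 against 657 ± 76.2 CPM) and less Tpsab1, a mast cell tryptase gene (log2 fold change -1.94 ± 0.13, SE). In edgeR 572 of 14261 genes passed, 185 higher and 387 lower in LAIR-1- cells, with a median change of 1.66-fold, and 197 changed at least 2-fold. Il10 lies on the plus strand of chromosome 1 (131019845 to 131024974), Tnfrsf8 on the minus strand of chromosome 4 (145267137 to 145315164) and Csf2 on the minus strand of chromosome 11 (54247271 to 54249667). Each gene named above passed with any 1 library left out. The count of 572 became 333 without LAIR-1+ 1, 369 without LAIR-1+ 2 and 374 without LAIR-1- 7.

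Of 18 effector cytokines, Il10 (3.73 ± 0.26, adjusted p = 2.80e-05) and Il4 (0.90 ± 0.13, adjusted p = 0.00215) rose, and Csf2 (-1.02 ± 0.09, adjusted p = 8.00e-05), Hbegf (-1.10 ± 0.20) and Csf1 (-1.03 ± 0.22, adjusted p = 0.0245) fell. These were 5 over all genes, with 7 adjusted over the list alone, and 2 fell in each fit with 1 library left out except that without LAIR-1+ 3, where 3 did. The other type 2 cytokines did not pass over all genes: Il5 changed by -0.14 ± 0.07, Il13 by 0.37 ± 0.14, Il9 by 1.18 ± 0.43 and Areg by 0.16 ± 0.09. Of 19 costimulatory genes, 6 rose, led by Tnfrsf8 (1.38 ± 0.07, adjusted p = 3.29e-06) and Tnfrsf9 (1.34 ± 0.08, adjusted p = 1.64e-05), and 2 fell, among them Il18rap (-0.74 ± 0.12); adjusted over the list alone 10 passed. The list passed towards higher values by camera (adjusted p = 0.000158, adjusted p = 0.141 with an estimated correlation), while its median was 0.036 and lay below 0 at a mean of at least 5 CPM (-0.014) and without LAIR-1+ 2 (-0.015) or LAIR-1- 10 (-0.015). Without LAIR-1+ 1 it held 3 genes that rose, and 1 member fell in each smaller fit except that without LAIR-1+ 2, where 2 did. Among chemokine receptors, Ccr4 (0.82 ± 0.09) and Ccr7 (1.09 ± 0.15), the lymph node homing receptor, rose, while the chemokines Ccl4 (-4.68 ± 0.55) and Cxcl3 (-1.05 ± 0.16) fell. S1pr1, which draws lymphocytes out of tissue, rose by 1.92 ± 0.22, and the transcription factor Lef1 by 1.52 ± 0.13. The adhesion receptor Cd44 changed by -0.47 ± 0.06.

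Among the largest changes, Ldoc1 (2.12 ± 0.35), B4galnt4 (1.43 ± 0.15) and Msc (1.37 ± 0.16) rose, and Sh3bgrl2 (-1.41 ± 0.13) and Ly6c1 (-1.45 ± 0.26) fell, each also with any 1 library left out. Dgat1, which makes triglycerides, rose by 0.49 ± 0.09 and held in the same way. Trf rose (1.39 ± 0.27), though not without LAIR-1+ 1 (adjusted p = 0.0580), LAIR-1+ 2 (0.0542) or LAIR-1- 10 (0.0545), and Ly6c2 fell (-1.46 ± 0.29), though not without LAIR-1+ 1 (0.0608) or LAIR-1- 10 (0.0552). The interferon-induced GTPase genes Tgtp1 (-2.07 ± 0.43) and Tgtp2 (-1.71 ± 0.34) fell. Neither passed without LAIR-1+ 1 (adjusted p = 0.0904 and 0.0779), LAIR-1+ 2 (0.0649 and 0.0538), LAIR-1- 8 (0.0724 and 0.0527) or LAIR-1- 10 (0.0839 and 0.0722).

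Inhibitory receptors and their ligands went both ways, with 4 of 18 higher and 2 lower over all genes and 10 past the list-alone test (list adjusted p = 0.658, adjusted p = 0.693 with an estimated correlation). Ctla4 rose (2.29 ± 0.43), from 0.680 to 3.32 CPM, and Ceacam1 fell (-2.55 ± 0.49, adjusted p = 0.0115), though not without LAIR-1+ 2 (adjusted p = 0.0621) or LAIR-1- 7 (0.0540). Of this list 1 rose and 2 fell without LAIR-1+ 1, 2 and 0 without LAIR-1+ 2, 1 and 0 without LAIR-1- 7, and 3 and 1 without LAIR-1- 10.

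Signalling genes went both ways. Of 19 JAK-STAT targets 4 rose and 1 fell over all genes, with 10 past the list-alone test, 4 up and 6 down (list adjusted p = 0.658, adjusted p = 0.693 with an estimated correlation). Pim2 (0.87 ± 0.10) and Socs3 (0.79 ± 0.12), targets of STAT transcription factors, rose, and Myc fell (-0.37 ± 0.08, adjusted p = 0.0175), though not without LAIR-1+ 1 (adjusted p = 0.113), LAIR-1+ 3 (0.0566), LAIR-1- 7 (0.104) or LAIR-1- 10 (0.0576). Of these targets 2 rose and 0 fell without LAIR-1+ 1, and 2 and 1 without LAIR-1- 7. Also higher were Bcl3 (0.62 ± 0.09), a regulator of NF-kappaB, and Cdk6 (0.49 ± 0.08). Pmaip1, which encodes the pro-apoptotic protein NOXA, rose by 1.01 ± 0.12. Dusp6 (-0.72 ± 0.07) and Spry1 (-0.50 ± 0.08), feedback inhibitors of ERK signalling, fell, as did the kinase Lyn (-0.60 ± 0.09), which phosphorylates inhibitory receptors. The list of AP-1, MAPK and immediate early genes fell (adjusted p = 0.0199, adjusted p = 0.308 with an estimated correlation), with 1 of 31 up and 4 down over all genes and over the list alone. It did not pass without LAIR-1- 7 (adjusted p = 0.110), at a mean of at least 5 CPM or at a mean of at least 50 CPM. Its 4 genes that fell were 2 without LAIR-1+ 1, 2 or 3 or LAIR-1- 7 or 8, and the 1 that rose did not pass without LAIR-1+ 2. Of 11 LAIR-1 signalling partners Lyn was the 1 that passed (list adjusted p = 0.0155, adjusted p = 0.252 with an estimated correlation).

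Among 26 ILC2 identity genes, 3 rose and 7 fell, with 11 past the list-alone test (list adjusted p = 0.00324, adjusted p = 0.180 with an estimated correlation). Klrg1 rose (0.57 ± 0.08) and Calcrl, a component of the receptor for calcitonin gene-related peptide, fell (-0.85 ± 0.11). Icos (0.31 ± 0.06, adjusted p = 0.0175) also rose, but not without LAIR-1+ 1 (adjusted p = 0.0881), LAIR-1+ 3 (0.0574) or LAIR-1- 7 (0.101). Il2ra (0.43 ± 0.09, adjusted p = 0.0187) rose, but not without LAIR-1+ 1 (0.0936), LAIR-1+ 3 (0.0616), LAIR-1- 7 (0.0566) or LAIR-1- 10 (0.0610). Arg1 fell (-0.28 ± 0.06, adjusted p = 0.0270), and passed in no smaller fit but that without LAIR-1- 8 (0.0835 without LAIR-1+ 1, 0.0946 without LAIR-1+ 2, 0.0783 without LAIR-1+ 3, 0.0981 without LAIR-1- 7 and 0.0892 without LAIR-1- 10). Of the 26, 1 rose and 2 fell without LAIR-1+ 1, 1 and 5 without LAIR-1+ 3, 1 and 3 without LAIR-1- 7, and 2 and 4 without LAIR-1- 10. Gata3 (-0.15 ± 0.06), Rora (-0.29 ± 0.08), Il1rl1 (-0.07 ± 0.10), Il7r (-0.09 ± 0.11), Pdcd1 (0.13 ± 0.06) and Mki67 (-0.14 ± 0.06) did not pass.

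Interferon-induced genes were lower in LAIR-1- cells. Of 19 tested, 7 fell over all genes and 14 adjusted over the list alone, and the log2 fold change was below 0 in all 19 (median -0.85, list adjusted p = 1.25e-12, adjusted p = 0.308 with an estimated correlation). The list did not pass by fry (adjusted p = 0.0841). Ddx58, the RNA sensor RIG-I, fell by 1.04 ± 0.12 on the log2 scale, Usp18 by 1.34 ± 0.22 and Gbp2 by 1.57 ± 0.29. The count of 7 was 3 without LAIR-1+ 1, and 4 without LAIR-1+ 2, LAIR-1- 8 or LAIR-1- 10. LAIR-1+ 1 had the highest level of several of these genes, with Gbp2 at 52.8 CPM against 41.6 and 22.1 in LAIR-1+ 2 and 3. Glycolysis and hypoxia response also fell as a list (adjusted p = 0.00814, adjusted p = 0.252 with an estimated correlation). Hk2, the inducible hexokinase (-0.71 ± 0.09), and Aldoa (-0.28 ± 0.06) fell over all genes, and 7 of 23 adjusted over the list alone. Aldoa did not pass without LAIR-1+ 1 (adjusted p = 0.0891), LAIR-1+ 3 (0.0537) or LAIR-1- 7 (0.105), and 1 list member fell without LAIR-1+ 1 or LAIR-1- 7. Oxidative phosphorylation genes rose as a list by a median of 0.09 (adjusted p = 0.0245, adjusted p = 0.579 with an estimated correlation) with 0 of 20 members past the edgeR threshold over all genes or over the list alone. The list did not pass without LAIR-1+ 1 (adjusted p = 0.179), LAIR-1+ 2 (0.123) or LAIR-1- 8 (0.131). The mitochondrially encoded mRNAs did not differ between the fractions (list adjusted p = 0.925, adjusted p = 0.950 with an estimated correlation).

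Transcripts of other cell types accompanied these groups. The epithelial keratin Krt8 was at 7.67, 8.63 and 8.80 CPM in LAIR-1+ 1, 2 and 3 and at 0 in all 3 LAIR-1- libraries, at least 187-fold lower against a floor of 3 counts over the group. Krt19 was at least 148-fold lower. Scgb1a1, the secretoglobin of airway secretory cells, was at 3.13, 76.8 and 28.9 CPM in LAIR-1+ 1, 2 and 3 and 0 in LAIR-1- (at least 847-fold lower), but did not pass with limma-voom (adjusted p = 0.173) or robust estimation of the spread (0.399). Of 6 epithelial markers tested 4 fell and 1 rose, Epcam (0.51 ± 0.13), over all genes and over the list alone. The median was -2.46, also with the genes absent from LAIR-1- cells set at their bound (list adjusted p = 1.23e-10, adjusted p = 0.141 with an estimated correlation). Epcam passed in no smaller fit but that without LAIR-1- 8, and the genes that fell were 2 without LAIR-1+ 2. Lyz2, the lysozyme of myeloid cells, was at 18.1 ± 6.13 and 1.44 ± 1.28 CPM (-3.77 ± 0.64, adjusted p = 0.00627). Lpl, a lipase gene high in alveolar macrophages, fell by 3.67 ± 0.69 on the log2 scale. Neither passed with DESeq2 (adjusted p = 0.212 and 0.262) or robust estimation (0.135 and 0.191). Of 10 macrophage and dendritic cell markers tested 2 fell over all genes, 1 without LAIR-1- 10, and 6 over the list alone (list adjusted p = 0.000921, adjusted p = 0.324 with an estimated correlation). Of 9 eosinophil, basophil and mast cell markers 1 rose, Ccr3 (2.23 ± 0.23), and 1 fell, Hdc (-2.45 ± 0.49, adjusted p = 0.0146), with 6 past the list-alone test (list adjusted p = 0.312, adjusted p = 0.581 with an estimated correlation). Hdc did not pass without LAIR-1+ 2 (adjusted p = 0.0769). The 1 neutrophil marker tested, Mmp8, fell (-4.01 ± 0.86, adjusted p = 0.0215), though not without LAIR-1+ 1 (adjusted p = 0.0984), LAIR-1+ 3 (0.0555), LAIR-1- 8 (0.0531) or LAIR-1- 10 (0.0756).

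Of 10 markers of NK cells and ILC1s, 2 rose over all genes, Gzma (3.21 ± 0.35) and Gzmb (from 19.3 to 54.8 CPM, adjusted p = 0.0143), and 6 passed the list-alone test, 3 up and 3 down (list adjusted p = 0.925, adjusted p = 0.950 with an estimated correlation). Gzmb did not pass without LAIR-1+ 1 (adjusted p = 0.0516), which leaves 1 that rose. Without LAIR-1+ 2, 3 rose and 1 fell, and 1 also fell without LAIR-1- 7 or LAIR-1- 10. Nkg7, Ifng and Ncr1 of that list fell by the list-alone test. Of 4 ILC3 markers Il22 rose (1.37 ± 0.30, adjusted p = 0.0229), with 2 past the list-alone test (list adjusted p = 0.103, adjusted p = 0.337 with an estimated correlation). Il22 did not pass without LAIR-1+ 1 (adjusted p = 0.0942), LAIR-1+ 3 (0.0617), LAIR-1- 8 (0.0637) or LAIR-1- 10 (0.105). Of 7 T cell markers Lat fell (-0.67 ± 0.10, adjusted p = 0.00320), the 1 past the list-alone test as well (list adjusted p = 0.925, adjusted p = 0.950 with an estimated correlation). The 1 endothelial or stromal marker tested, Pecam1, rose (0.71 ± 0.10, adjusted p = 0.00215). Ighm (23.8 CPM) and Igkc (17.9 CPM), immunoglobulin genes, appeared in LAIR-1- 7.

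With all 12 libraries in 1 fit, which applies 1 estimate of the spread to both experiments, 54 genes passed between the fractions, all of them among the 572, and Lair1 did not (adjusted p = 0.570). Tested against a 1.2-fold change in edgeR 283 genes passed, and DESeq2 called 862.

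The third comparison asked whether losing LAIR-1 by genotype and lacking it on the surface went with the same genes. The labels name no sort by LAIR-1 for the WT libraries, so the reference groups, WT and LAIR-1+, are not alike. Of 12830 genes tested in both, Pxdc1 was the 1 gene past the adjusted threshold in both, lower in each (-1.32 ± 0.09 in KO and -0.29 ± 0.07 in LAIR-1- cells); DESeq2 gave 60 genes in the same direction. At an unadjusted p under 0.05, 96 genes were higher in both where 32.7 would be shared if the comparisons were independent (two-sided Fisher exact p = 2.35e-22) and 167 were lower in both where 56.5 would be (p = 1.83e-40, Fisher exact). Genes higher in KO and lower in LAIR-1- cells numbered 44 (50.6 for independent comparisons, Fisher exact p = 0.365), and the reverse 23 (36.5, Fisher exact p = 0.0178). Genes are not independent replicates, so these p-values describe genes rather than samples. The shared higher genes include Tnfrsf8, Tnfrsf9, Lef1, Ccr4, Il13, Il9 and Cdk6, and the shared lower genes Prnp, Ramp1, Lpcat2, Sh3bgrl2, Ctsd, Nqo1 and Ly6a. Across the 12830 genes the log2 fold changes had Pearson r = 0.0911 and Spearman rho = 0.106, and across the 490 genes that passed between the fractions at a mean of at least 5 CPM, r = 0.501 and rho = 0.422.

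**Figure D2:**
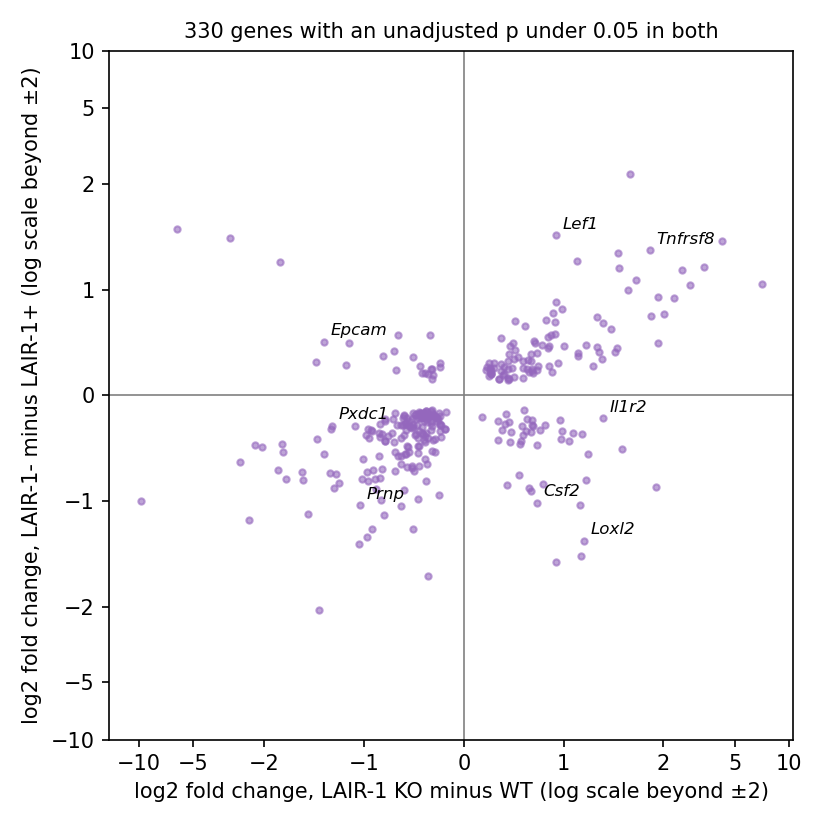
The 330 genes at an unadjusted p under 0.05 in both comparisons, as log2 fold change of KO minus WT (horizontal) against LAIR-1- minus LAIR-1+ (vertical); both axes are linear up to 2 and logarithmic beyond. Of these genes 96 lie in the upper right, 167 in the lower left, 44 in the lower right and 23 in the upper left.

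The difference between the comparisons was tested in 1 fit of the 12 libraries, as the change in KO against WT minus the change in LAIR-1- against LAIR-1+. It passed for 29 of 15125 genes, 17 with the larger value in KO against WT and 12 with the smaller. Csf2 differed most clearly, by 1.76 ± 0.14 (adjusted p = 0.000412): 0.74 ± 0.10 in KO against -1.02 ± 0.09 in LAIR-1- cells. Il1r2 differed by 1.62 ± 0.17 (adjusted p = 0.00292) and Pxdc1 by -1.02 ± 0.10 (adjusted p = 0.00292); these 3 passed with any 1 of the 12 libraries left out. Loxl2, a lysyl oxidase-like gene that cross-links collagen, differed by 2.60 ± 0.31 (adjusted p = 0.0105), and P4ha2, a subunit of the enzyme that hydroxylates collagen prolines, by 1.54 ± 0.20 (adjusted p = 0.0147), but neither passed without LAIR-1+ 1, LAIR-1+ 3 or LAIR-1- 7 (highest adjusted p 0.0717 and 0.0726). The count of 29 ranged from 3 without LAIR-1+ 1 or LAIR-1- 7 to 236 without WT 11. It was 6 without WT 10 or LAIR-1+ 2, 45 without KO 13, 4 without LAIR-1+ 3, 9 without LAIR-1- 8 and 8 without LAIR-1- 10. The experiments also differ in the sex-linked transcripts, and a difference in response between the sexes cannot be told apart from these values.

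**Figure D3:**
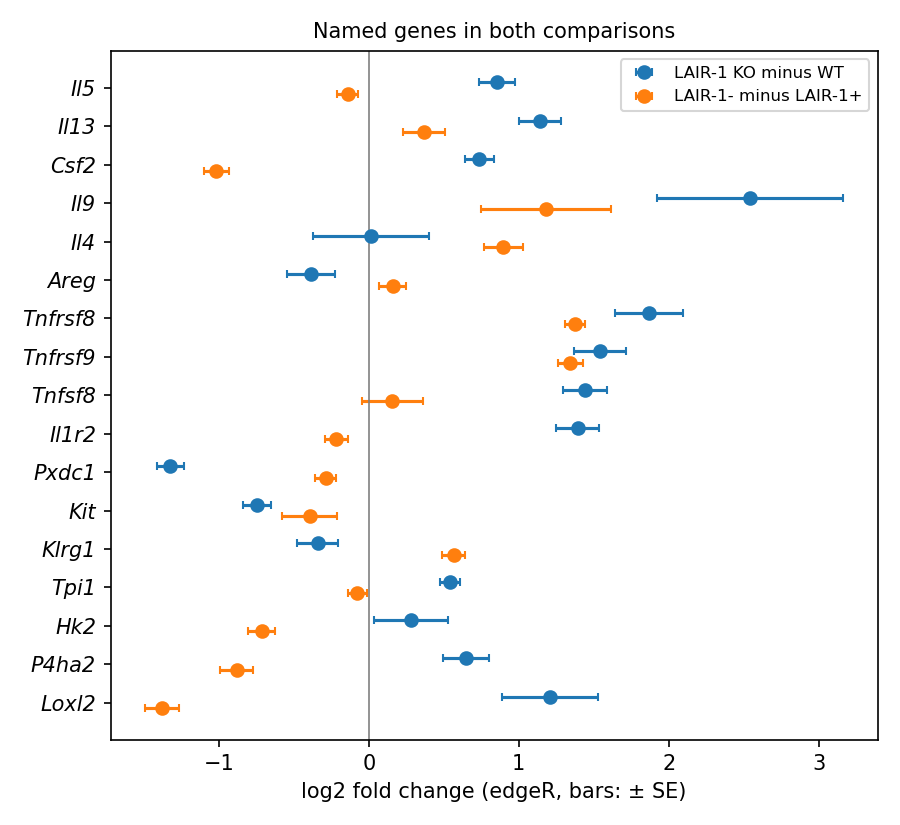
Log2 fold change of 17 named genes in KO minus WT (blue) and LAIR-1- minus LAIR-1+ (orange), on a linear axis; points are edgeR estimates and bars their SE (n = 3 per group). Tnfrsf8 and Tnfrsf9 lie above 0 in both, and Csf2 at 0.74 and -1.02.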

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

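Chosen after the result was seen were the tests of keratin and macrophage transcripts, the fits with 2 libraries left out, the simulations with libraries left out, the left-out libraries in the effect ratio, the test of a wrong WT label for KO 15, the allowance for spread in the other KO 15 test, and the CPM filter of 50. The change in KO against WT differed from that in LAIR-1- against LAIR-1+ for 9 of the named genes by the direct test in edgeR. Csf2 differed by 1.76, Il1r2 by 1.62 and Pxdc1 by -1.02, each with any library left out. Loxl2 differed by 2.60 and P4ha2 by 1.54, neither past the threshold without LAIR-1+ 1, LAIR-1+ 3 or LAIR-1- 7. Calcrl differed by 1.30 (0.44 in KO, -0.85 in LAIR-1- cells), past the threshold in 5 of the 12 fits with 1 library left out (adjusted p 0.00364 to 0.0848). Il5 differed by 1.01 (3 of 12, adjusted p 0.00524 to 0.116), Dusp6 by 0.59 (2 of 12, 0.00873 to 0.171) and Klrg1 by -0.90 (3 of 12, 0.0278 to 0.219). Each of these 4 was past the threshold without WT 11 and not without WT 10, LAIR-1+ 1, LAIR-1+ 2, LAIR-1+ 3, LAIR-1- 7, LAIR-1- 8 or LAIR-1- 10.

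The first pattern is that 1 gene passed in KO against WT and 572 between the sorted fractions. Lower depth is argued against. After each sorted library was thinned to the total of the shallowest WT or KO library (WT 10), 569 genes passed, against 572 before. A smaller effect of losing LAIR-1 did not show over 4048 genes with a mean of at least 50 CPM. After removing error, the SD of the effects was 0.157 between the fractions and 0.194 in KO against WT, a ratio of 0.807. Its 95% interval over resampled genes was 0.744 to 0.884, and it was 0.670 to 0.915 over 3894 genes with 1 library left out. The root mean squared SE was 0.0986 between the fractions and 0.192 in KO against WT, there about as large as the effect SD. Resampling genes leaves out the spread between libraries, and a deviation that many genes of 1 library share can count as effect. With 3 libraries per group the ratio therefore cannot exclude a smaller effect. The reference groups also differ, since the labels name no sort by LAIR-1 for the WT libraries. It also stays open that uneven detection of weak genes may widen the shared estimate of the spread. At a mean of at least 50 CPM 55 genes passed, between the bounds of 20 and 100. That filter was chosen after the data were seen, so these bounds are no criterion of the original plan. Libraries out of place also stay open. With 1 WT or KO library left out edgeR called 0 genes at most (956 to 1560 at an unadjusted p under 0.05, the highest without WT 11). With 1 WT and 1 KO library left out it called 1 at most. Both counts were under the bound of 50 set for excluding this, while DESeq2 called 322 genes with all libraries. In simulated counts, fits with 1 library left out recovered a median of 26.1% of 2-fold and 70.5% of 4-fold changes. Those with 1 WT and 1 KO library left out recovered 2.99% to 23.9% and 56.1% to 68.2%. The simulation took its spread from all 6 libraries, so it cannot tell what a fit without a misplaced library would recover. The biological coefficient of variation was 0.523 to 0.582 with 1 left out against 0.505. Those fits tested 14730 to 14965 genes against 14164. The coefficients thus cover unlike sets of genes and cannot tell whether a removal lowered the spread. The count of the difference was 236 without WT 11 against 29.

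The second pattern is keratin and myeloid transcripts in LAIR-1+ libraries. Airway secretory cells as the main source of Krt8 are argued against, since Scgb1a1 differed 24.9-fold between the 3 LAIR-1+ libraries where Krt8 differed 1.16-fold, and their ratio varied 21.8-fold. For Krt18 and Krt19 this stays open: they differed 2.13-fold and 3.01-fold and their ratios to Scgb1a1 varied 11.7-fold and 8.27-fold, but both were lowest in LAIR-1+ 1 and highest in LAIR-1+ 2, as Scgb1a1 was. Macrophages are a candidate source of Lyz2, Lpl, Cd36, Cd14 and Chil3: 5 of the 13 listed macrophage and dendritic cell markers (of 20) were higher in every LAIR-1+ library than in any LAIR-1- library (Lyz2, Cd14, Cd68, Chil3 and Xcr1), which leaves it open. Chance gives this order for 1 marker in 20. Means in LAIR-1+ and LAIR-1- cells were 42.2 and 36.7 CPM for Xcr1, 9.64 and 6.41 for Cd68, and 0.871 and 0.0174 for Cd14. They were 77.0 and 11.4 CPM for Chil3, and 18.1 and 1.4 for Lyz2. Chil3 was at 31.9, 70.2 and 128 CPM in LAIR-1+ 1, 2 and 3, Cd74, of antigen-presenting cells, was at 15.3 in LAIR-1+ and 16.9 in LAIR-1-, the labels do not give the sorting gate, and expression of these genes by LAIR-1+ ILC2s themselves remains untested.

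The third pattern is Lair1 in the library labelled KO 15, at 43.8% of the WT mean. A WT library with a wrong label is argued against: placed between KO (0) and WT (1) over 50 genes chosen without it, KO 15 was at 0.154, below the WT libraries (0.660 to 1.05). WT cells or RNA mixed into it remain a candidate explanation, since its place minus the mean of KO 13 (0.383) and KO 14 (-0.0142) was -0.0302 with an SE of 0.344. That value is below the bound of 0.2 set beforehand for excluding it, and the allowance for its spread, made after it was seen, keeps it open. No biological explanation was tested.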

How the results depend on the processing

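Chosen after the data were seen were the filters at a mean of at least 20 and 50 CPM, robust estimation, and the alternatives for the unadjusted overlap and for the glycolysis list of the difference. KO against WT gave 1 gene with either other size factor, no filter, the 1.2-fold test, limma-trend at both offsets or robust estimation. It gave 5 genes at a mean of at least 5 CPM, 34 at 20, 55 at 50, 2 with limma-voom, 322 with DESeq2 and 267 with all 12 libraries in 1 fit; leaving out 1 library gave 0 each time. The 8 lists became 0 with an estimated correlation and 4 with fry. LAIR-1- against LAIR-1+ gave 526 to 671 genes with other size factors, no filter, 5 CPM, limma or robust estimation. It gave 388 at 20 CPM, 862 with DESeq2, 54 with all 12 libraries, 283 with the 1.2-fold test and 250 at 50 CPM, which tests 4411 genes; leaving out 1 library gave 333 to 516. Its 9 lists became 0 with an estimated correlation. With fry 9 also passed, but not the same ones. Interferon response (adjusted p = 0.0841 by fry), macrophage and dendritic cell markers (0.0841) and oxidative phosphorylation (0.287) did not pass there. Lair1 was -3.18 with all 12 libraries, no longer past the threshold. The overlap of 1 became 60 with DESeq2, 3 at 5 CPM, 12 at 50 CPM and 263 at an unadjusted p; that 263 lay between 186 and 274 with 1 library left out and was 169 at 50 CPM. The difference of 29 became 28 with other size factors, 36 at 5 CPM, 254 with DESeq2, 52 at 50 CPM and 3 to 236 with 1 library left out. Directions reversed in genes near 0 that had not passed: Icos in KO against WT was 0.00 (0.00197) with limma-voom and ranged from -0.14 to 0.17 with 1 library left out, Il4 from -0.27 to 0.33 and Arg1 from -0.18 to 0.041. Between the fractions Il1rl1 ranged from -0.15 to 0.022 and Il7r from -0.19 to 0.021. The cause was not tested for any of these. Of 1043 values of named genes between the fractions under other settings, 937 kept direction and call, 104 lost the call and 2 gained it; with 1 library left out 426 of 522 did and 91 lost it. Thinning the sorted libraries gave 569 genes against 572. What depth limits for Lair1 was not tested: its 9, 0 and 67 counts in KO 13, 14 and 15 came at totals of 20878649, 19777984 and 20637817.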

Other observations

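The list tests of the difference were chosen after the result was seen, while the test of genes flanking Lair1 and the splits of the samples were planned. Of 30 lists tested on the difference between the comparisons, glycolysis and hypoxia response was the 1 that passed with an estimated correlation as well. The test uses the same libraries as the 2 comparisons and is not independent of them; there the list passed with the preset correlation, up in KO and down in LAIR-1- cells, and not with an estimated one (adjusted p = 0.0945 and 0.252). For 22 of 23 genes the change was larger in KO against WT than in LAIR-1- against LAIR-1+ (median difference 0.27 on the log2 scale, adjusted p = 9.46e-09, adjusted p = 0.00425 with an estimated correlation). Tpi1, the triosephosphate isomerase gene, was 0.54 ± 0.07 in KO and -0.08 ± 0.06 in LAIR-1- cells and differed by 0.63 ± 0.08 (adjusted p = 0.0147). Hk2 was 0.28 ± 0.25 and -0.71 ± 0.09, Pfkl 0.43 ± 0.10 and -0.18 ± 0.07, and Slc16a3, a lactate exporter, 0.23 ± 0.11 and -0.30 ± 0.08. Tpi1 was the 1 member past the threshold, and not without WT 10, LAIR-1+ 1, LAIR-1+ 3, LAIR-1- 7 or LAIR-1- 10 (highest adjusted p 0.0726). The list passed with any 1 library left out, with medians of 0.20 to 0.33 and adjusted p of 3.58e-09 to 1.27e-06 (0.00625 to 0.0277 with an estimated correlation). A difference in response between the sexes is untested.

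Another 7 lists differed between the comparisons with the preset correlation and not with an estimated one. The mitochondrially encoded mRNAs, a measure of RNA quality, moved in the same direction as glycolysis, with 13 of 13 above 0 (median 0.44, adjusted p = 6.68e-06, adjusted p = 0.410 with an estimated correlation). Larger in KO against WT were also effector cytokines (adjusted p = 0.00178, adjusted p = 0.184 with an estimated correlation), the unfolded protein and integrated stress response (0.00324 and 0.225), interferon response (0.00845 and 0.409) and costimulatory receptors (0.0287 and 0.316). Smaller were oxidative stress defence (0.00178 and 0.316) and oxidative phosphorylation (0.00994 and 0.459). Larger here means the higher value and need not be a rise. Median changes were below 0 in both comparisons for interferon response (-0.22 in KO, -0.85 in LAIR-1- cells) and oxidative stress defence (-0.30, -0.00052). They were above 0 in both for effector cytokines (0.74, 0.095), the unfolded protein and integrated stress response (0.24, 0.057) and costimulatory receptors (0.49, 0.036).

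Flanking sequence carried along with the targeted allele could change genes beside Lair1 in KO mice. Of 84 tested genes within 10 Mb, 4 (4.76%) had an unadjusted p under 0.05, against 8.39% of other genes (odds ratio 0.546, 95% interval 0.145 to 1.46, two-sided Fisher exact p = 0.321), which argues against it as a source of many of the changes.

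Other splits of the same samples were run through the same tests. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In KO against WT the real split gave 1 gene and the highest other 0, and 8 lists against 4; 1 of the 10 splits, the real one, gave as many genes, and 1 as many lists. Between the sorted fractions the real split gave 572 genes and the highest other 0, and 9 lists against 3, again 1 of 10 splits for each. For the comparisons together 100 splits were counted. For the overlap of 1 gene they decide nothing (1 of 100, highest other 0), since every other split of either comparison called 0 genes by edgeR and so fixed its overlap at 0. Chance in the grouping of both experiments at once can be excluded for the overlap of 263 genes at an unadjusted p (1 of 100, highest other 75) and for the 29 genes of the difference (1 of 100, highest other 16). Both of these highest others kept the sorted groups, and splits that keep them are too few for a share under 0.05. The count of the difference was below 16 in 7 of the 12 fits with 1 library left out: 3 without LAIR-1+ 1 or LAIR-1- 7, 4 without LAIR-1+ 3, 6 without WT 10 or LAIR-1+ 2, 8 without LAIR-1- 10 and 9 without LAIR-1- 8, while it was 236 without WT 11 and 45 without KO 13. In simulated counts the same test called 27 unchanged genes, beside 10, 49 and 101 genes it recovered that differed by 1.5-, 2- and 4-fold. Its adjusted threshold of 0.05 was thus not held there.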
